A study of Mus musculus with 6 samples.

How the data were processed

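Microglia were sorted from the brains of 6 mice, 3 given saline and 3 given methamphetamine, and libraries were made with a targeted amplicon panel for mouse transcripts and sequenced on an Ion Torrent instrument, per the labels' protocols. The panel amplifies a short stretch of each gene, so a value does not depend on transcript length as whole-transcript sequencing does, but it depends on how well each primer pair works, so a low value can come from a poor primer pair as well as from a low transcript level, and gives no information on isoforms. Aligner, genome build, counting, normalization and the statistical model are not given in the sources used here, and no coordinates are printed for that reason.

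The single file used is the authors' deposited table of the comparison. Per the file headers, it holds the authors' group averages on a log2 scale, 1 for Meth and 1 for Saline. The deposited fold change is a signed linear ratio of Meth over Saline, with a negative sign where Saline is higher, and it equals the difference of the log2 averages within 0.017. Per the file headers, each gene also has the authors' p-value and FDR adjusted p-value. A Benjamini-Hochberg adjustment of the deposited p-values differs from the deposited FDR by at most 0.0023, as far as their rounding allows. The sum over genes of 2 to the power of the average, minus 1, is 981392 for Meth and 1012049 for Saline, so the scale is read here as log2 of RPM plus 1, with RPM the reads of a gene scaled to a fixed library total; that reading comes from the values, not from a header. Averages below 0 occur for 1425 genes in Saline (lowest -0.33) and 14 in Meth (lowest -0.01), while 6844 genes are at 0 in both groups. The table has 0 columns of values per sample. Depth per library is therefore unknown, no standard deviation or interval can be given, and neither the similarity of the replicates nor duplicate libraries could be examined. A fold on the log2 of a value plus 1 understates the change of low genes.

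Genes are named by the symbols of the table. In 4 rows the name is a date, as spreadsheet software makes of some symbols, and these rows were counted but not named. Of the 23930 symbols, 21366 (89.3%) matched a gene name of GENCODE mouse release M21, which was used only for exon numbers, biotype, GC content and length of the longest transcript. Genes absent from the table, such as Nfkb1, Isg15, Gapdh and Pcna, were not analysed here.

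The comparison was fixed before the data were examined: with only the authors' comparison at hand, genes were called at a deposited FDR adjusted p under 0.05, with the deposited fold as it stands. Named genes were, in each direction, the 12 called genes with the largest fold whose average in the higher group lay above that of the median gene (0.37), leaving out predicted genes and chemosensory receptors. To these were added up to 4 members of each list with the smallest p, and Tnf, Il1b, Tnfrsf1a, Tnfrsf1b, P2ry12, Tmem119, Cx3cr1, Aif1, Cd68, Trem2, Apoe, Itgam, Ptprc and Mrc1 in any case. The text gives values for part of the list members taken by this rule.

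There were 30 gene lists with 640 genes, of which 578 were in the table, fixed before the data were examined. For each list the median of the Meth minus Saline log2 averages was set against the medians of 10000 random lists of the same size, each member being replaced by a gene among the 200 nearest in mean level. The percentile describes these libraries and is no p-value. Counts adjusted over the list alone use a Benjamini-Hochberg adjustment of the deposited p-values within the list. Marker shares are sums of 2 to the power of the average, minus 1, as a percentage of the sum over all genes, and no test of them was possible with 1 value per group. The trend with GC content and transcript length was removed as the running median over 20 bins, in genes with either average of at least 1.

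To examine which model could give the deposited averages and p-values of genes near 0, all 21 ways of splitting 3 Saline and 3 Meth libraries by a further factor that still allow a fit were enumerated, and the averages and moderated p-values each implies for a gene read in a single library were computed. This step and the list percentiles were tested on simulated data. On 6 libraries simulated with 1 factor, 3 Saline and 1 Meth against 2 Meth, and fitted with limma 3.58.1, 2 of the 21 designs matched. These were the true design and a design with the same fit to these genes. No other factor was simulated, and the averages required for a match were fixed beforehand. The true design was thus not missed, but whether other designs would be told apart was not tested. A simulated list of 22 genes shifted by -0.6 on the log2 scale among 10375 genes lay at percentile 0.8. Of 100 unshifted lists, 3 lay outside the central 95%. For these lists the differences were shuffled over genes, so lists whose members vary together were not covered. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and R 4.3.3.

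Alternatives were an adjusted p under 0.1, a minimum fold of 1.5, an unadjusted p under 0.05, adjustment of the deposited p-values over other sets of genes, random lists not matched on level, the mean in place of the median, members above the median level only, and marker shares without the 50 most abundant genes.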

Results

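Gene expression was measured in microglia, the resident macrophages of the brain, that were sorted by flow cytometry from adult C57BL/6 mice after perfusion. The gate kept cells with CD11b (Itgam), low CD45 (Ptprc) and no CD206 (Mrc1). There were 3 mice given saline (Saline) and 3 mice given methamphetamine (Meth), a psychostimulant that releases monoamines, as 4 injections of 5 mg/kg at intervals of 2 h. RNA was read by a targeted amplicon panel, in which each gene is amplified by its own primer pair. The values analysed are those of the authors' deposited table, which lists 23930 genes with 1 average per group on a log2 scale, a signed fold change, a p-value and a false discovery rate (FDR) adjusted p-value. It holds no values per mouse, so no spread between mice and no sequencing depth stand behind any value below. Group averages, folds and p-values of single genes are the authors' own unless a value is said to be computed here.

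The comparison of Meth with Saline asks which transcripts of microglia differ after methamphetamine. In the authors' deposited table, 536 genes had an adjusted p under 0.05, 515 of them higher in Meth and 21 lower. Transcripts of measurable abundance formed a small part of these: 37 genes reached a log2 average of at least 1 in either group, 16 higher and 21 lower. The other 499 genes (93.1%) lay under 1 in both groups, and 484 of the 536 had a Saline average below 0. Of the called genes, 118 were chemosensory receptors and 154 were predicted genes or clones.

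Of the 21 genes called lower, the authors' deposited table gave the largest fold for Hlf, a circadian output transcription factor, with a log2 average of 1.80 in Meth and 3.74 in Saline (3.82-fold lower, adjusted p = 0.0007). Tk2, the mitochondrial thymidine kinase, was 3.31-fold lower (adjusted p = 0.0209) in the authors' deposited table. Ears2, the mitochondrial glutamyl-tRNA synthetase, was 2.52-fold lower in the authors' deposited table (adjusted p = 0.0268). Also lower in Meth in the authors' deposited table were Srl (2.79-fold), Zfp213 (2.32-fold), Txndc9 (2.18-fold), Cdr1 (2.12-fold), Mettl25 (2.01-fold), the small GTPase Rap1a (1.92-fold), Gstt2 (1.77-fold), the ether lipid monooxygenase Agmo (1.54-fold) and the transcriptional coregulator Cited2 (1.54-fold). In the other direction, Dctd, which deaminates deoxycytidylate, was 3.25-fold higher (4.32 against 2.62, adjusted p = 0.0386), and Chaf1a, a subunit of the histone chaperone that acts at replication forks, was 1.89-fold higher (adjusted p = 0.0430) in the authors' deposited table. The authors' deposited table listed as higher the fibronectin receptor subunit Itga5 (2.33-fold, adjusted p = 0.0052), the endolysosomal channel Tpcn2 (2.27-fold) and the vasoactive intestinal peptide receptor Vipr1 (2.24-fold). Higher in the authors' deposited table were also the ribosome assembly factor Wdr75 (2.00-fold), Nipsnap1 (1.86-fold), the kinase Pkmyt1 (1.84-fold) and the deubiquitinase Fam63a (1.72-fold). The rule for named genes also took Bcl2l14 (2.16-fold), Tbc1d10c (1.72-fold) and Xkr4 (1.63-fold) from the authors' deposited table, each under a log2 average of 1 in Meth and below 0 in Saline.

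The calls on abundant genes depended on the many genes near 0. When the deposited p-values were adjusted here by the Benjamini-Hochberg method over the 10375 genes with either average of at least 1, none of the 37 kept an adjusted p under 0.05, with the lowest value at Hlf (0.0685). Of these 10375 genes, 1520 had an unadjusted p under 0.05 in the authors' deposited table (670 higher and 850 lower). By chance 519 would, if the p-values are valid. Without values per mouse, this excess cannot be assigned to the treatment rather than to a single deviating library.

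**Figure D1:**
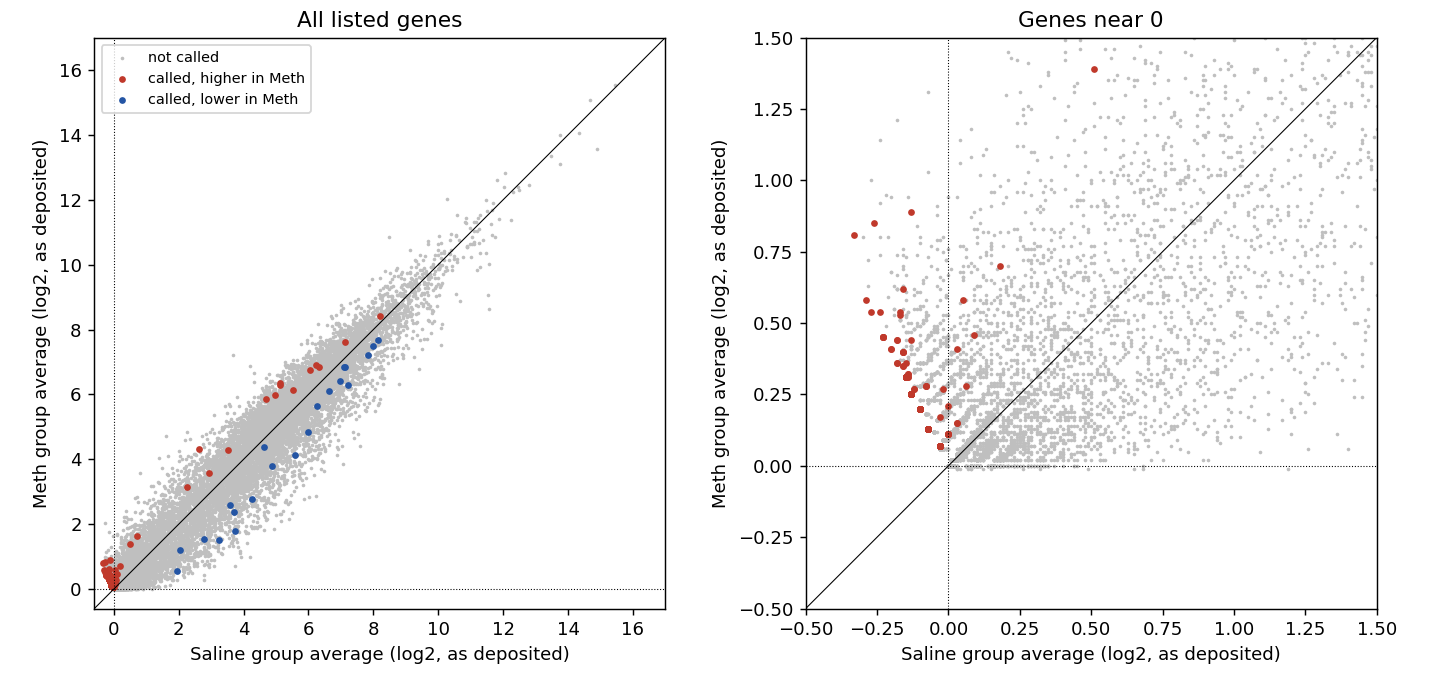
Each point is 1 gene of the authors' deposited table, with its Saline group average on the x axis and its Meth group average on the y axis (both log2, as deposited), for all genes (left) and for genes near 0 (right). Red and blue mark genes with an adjusted p under 0.05 that were higher (515) or lower (21) in Meth; 484 of these calls lie left of the dotted line at a Saline average of 0.

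Genes of the homeostatic state of microglia were lower in Meth as a group. Of the 22 members in the authors' deposited table, 17 were lower and 4 higher, with a median log2 difference of -0.61 (Meth minus Saline), below all 10000 random lists matched on expression level, whose central 95% ran from -0.29 to 0.26. Unadjusted p-values under 0.05 were listed for 7 members, all lower. Among them in the authors' deposited table were the adhesion receptor Adgrg1 (8.50 against 9.81, unadjusted p = 0.0126), Mef2a (9.09 against 9.56), Gpr34 (10.24 against 11.01), the TGF-beta receptor Tgfbr1 (a 1.52-fold difference) and the microglial membrane protein Tmem119 (10.85 against 11.75, unadjusted p = 0.0454). The fractalkine receptor Cx3cr1 stood at 10.66 against 11.27 in the authors' deposited table, and the purinergic receptor P2ry12 at 9.20 in both groups. No member had an adjusted p under 0.05, over all genes or adjusted over the list alone (0 of 22). The averages of genes near 0, described under other observations, leave open that all deposited differences rest on 1 Meth library.

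Genes of activated or disease-associated microglia were higher in Meth as a group. The authors' deposited table listed 17 of the 25 members higher and 7 lower, with a median log2 difference of 0.42, at percentile 99.94 of the matched random lists (central 95% from -0.24 to 0.26). Lpl, the lipoprotein lipase, had a log2 average of 7.23 in Meth and 3.66 in Saline in the authors' deposited table, an 11.88-fold difference that missed the threshold (adjusted p = 0.0913). Unadjusted p-values under 0.05 were listed for 7 higher members and 1 lower one, and the higher ones included the growth factor Csf1 (7.27 against 6.36), the lysosomal protease Ctsd (15.07 against 14.68) and the galectin Lgals3 (2.64 against 1.47). Apoe stood at 6.41 against 4.81 (unadjusted p = 0.1014), Trem2 at 10.44 against 9.99 (0.2029) and Cd68 at 11.31 against 10.81 (0.1493) in the authors' deposited table. Aif1, which is not in the list, stood at 9.84 against 9.51 (unadjusted p = 0.3743) in the authors' deposited table. No member had an adjusted p under 0.05, over all genes or adjusted over the list alone (0 of 25). The limit given for the homeostatic list, that the differences may rest on 1 Meth library, holds here too. Across the 9965 genes with either average of at least 1 and a matched transcript, the deposited log2 difference was larger at higher transcript GC content (Spearman's rho 0.21, across genes, which are not independent replicates). With the trend in GC content and length removed, the percentile of the activation list was 98.78 or 94.96, depending on the genes the trend was fitted on, and that of the homeostatic list stayed at or under 0.01.

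**Figure D2:**
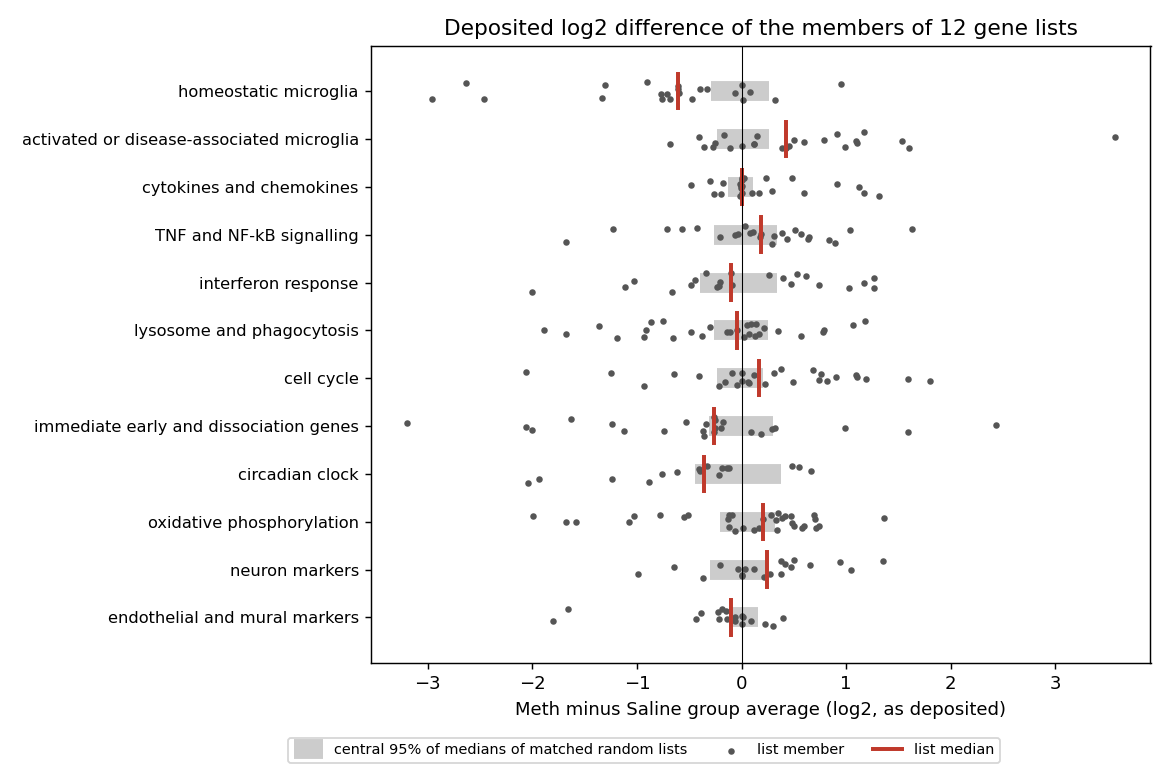
Points are the members of 12 gene lists, placed on the x axis by the Meth minus Saline difference of the log2 group averages in the authors' deposited table. Red lines mark list medians and grey bars the central 95% of the medians of 10000 random lists matched on level; the median of homeostatic genes (-0.61) lies below its bar and that of activation genes (0.42) above.

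Tumour necrosis factor (TNF), which the title of the series names as a product of astrocytes, had a gene listed near 0 in both groups. The authors' deposited table listed Tnf at 0.24 in Meth and 0.72 in Saline (unadjusted p = 0.3586), and its receptors Tnfrsf1a at 7.42 against 8.65 (unadjusted p = 0.0994) and Tnfrsf1b at 9.73 against 9.62. In the authors' deposited table, C1qa stood at 0.41 against 0.28 beside its partner subunit C1qb at 12.83 against 12.05, and the ferritin gene Fth1 at 0 in both groups. A primer pair that gives few reads cannot be separated from a low transcript level. Il1b, the interleukin-1 beta gene, stood at 3.12 against 1.81 in the authors' deposited table (unadjusted p = 0.0220, adjusted p = 0.3728). The cytokine and chemokine list had 11 members higher and 8 lower of 24, a median of 0.00 and percentile 54.38, and 3 members (Csf1, Il1b and Cxcl16), all higher, had an unadjusted p under 0.05 in the authors' deposited table. The percentile of the cytokine list was 98.06 with the mean in place of the median, and 98.35 or 98.54 with the GC and length trend removed in either way. The list of TNF and NF-kB signalling had a median of 0.19 and percentile 82.02 (99.9 with unmatched random lists), with the inhibitor Nfkbia at 7.56 against 6.72 (adjusted p = 0.1260) and Nfkbiz at 6.01 against 6.58 in the authors' deposited table. Neither list had a member with an adjusted p under 0.05, over all genes or adjusted over the list alone.

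Immediate early and dissociation genes, which respond within minutes to stimulation or tissue handling, lay at percentile 4.65 with a median of -0.26. Their percentile was 0.01 with unmatched random lists, 1.71 with the mean, and 1.72 or 1.16 with the GC and length trend removed. In the authors' deposited table, 17 of 24 were lower and 7 higher, and the RNA-binding regulator Zfp36 (3.85 against 7.05), Klf2 (3.05 against 5.11) and Klf4 (0.69 against 2.32) had an unadjusted p under 0.05. The circadian clock list had 13 of 16 members lower, a median of -0.36 and percentile 6.17 (0.05 with unmatched random lists). Besides Hlf, the clock output gene Dbp (2.45 against 3.69) and the repressor Nr1d2 (7.62 against 8.02) were lower, and Nr1d1 (4.05 against 3.50) was higher, at an unadjusted p under 0.05 in the authors' deposited table. Hlf alone passed when adjusted over the list alone (1 of 16). The cell cycle list had 17 members higher and 9 lower of 28, a median of 0.17 and percentile 94.82. It lay at 99.86 with unmatched random lists, 98.85 with the mean, 97.82 with members above the median level and 99.83 with the trend of genes at 3 or above removed, but at 93.32 with that of genes at 1 or above. The replicative helicase subunits Mcm5 (4.10 against 2.30, adjusted p = 0.0613) and Mcm6 (5.91 against 4.32, adjusted p = 0.0607) headed it in the authors' deposited table. Of the list, 3 members (Mcm5, Mcm6 and Cenpf) passed when adjusted over the list alone, against 0 over all genes, with Cenpf near 0 (0.28 against -0.10) in the authors' deposited table.

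The other functional lists lay inside the central 95% of matched random lists. Lysosome and phagocytosis moved to percentile 1.22 with the GC and length trend of genes at 3 or above removed from all genes, and 7 of these lists lay outside with random lists not matched on level. Percentiles were 33.58 for the interferon response, 70.35 for antigen presentation, 43.12 for lysosome and phagocytosis, 52.87 for glucocorticoid-induced genes, 87.0 for the unfolded protein and integrated stress response, 33.71 for the antioxidant response and 83.87 for oxidative phosphorylation. They were 61.4 for glycolysis and hypoxia, 13.39 for cholesterol metabolism, 17.1 for actin cytoskeleton and motility, 75.6 for glutamate receptors and transport, 34.85 for monoamine receptors and methamphetamine targets, 86.84 for ribosomal proteins and 46.18 for sex-linked transcripts. Median and mean differed in sign for interferon response (-0.10 and 0.04), oxidative phosphorylation (0.20 and -0.01) and glycolysis and hypoxia (0.05 and -0.05). Single members with an unadjusted p under 0.05 in the authors' deposited table included the guanylate-binding proteins Gbp5 (4.10 against 5.13) and Gbp2 (2.14 against 3.25), both of the interferon list, the scavenger receptor Cd36 (1.42 against 0.24, adjusted p = 0.1019) and the lysosomal membrane protein Scarb2 (5.75 against 7.43). Of antigen presentation genes at that threshold in the authors' deposited table, 3 were lower, Tap2 (6.48 against 7.52), Cd80 (4.19 against 4.89) and B2m (10.54 against 10.90), and 1 was higher, the invariant chain Cd74 (6.50 against 5.78). Of sterol synthesis genes, Mvd was higher (4.06 against 2.38) and Mvk lower (1.66 against 2.04) in the authors' deposited table. None of these lists had a member with an adjusted p under 0.05 over all genes, and adjusted over the list alone only the monoamine list had any (2 of 22, Htr7 and Slc6a2, both under 1 in the authors' deposited table). Of the 34 ribosomal protein genes in that list, 14 were listed.

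Markers of other cell types made up a small share of the summed values in both groups. All marker lists together held 0.271% of the sum in Meth and 0.277% in Saline, computed from the averages of the authors' deposited table, and border-associated macrophage markers took most of it (0.199% and 0.177%). Within that list, Maf (9.71 against 10.15) and Stab1 (9.94 against 9.15), which differed in opposite directions in the authors' deposited table, held 0.185% and 0.168% of the sum. Cd163 (0.06 against -0.02) and Pf4 (0.21 against 0.34) were near 0 in the authors' deposited table. Astrocyte markers took 0.0294% in Meth and 0.0489% in Saline, and lymphocyte markers 0.00773% and 0.0129%. Of the gate's own genes, Itgam stood at 11.66 against 11.49, Ptprc at 7.77 against 7.78 and Mrc1 at 4.80 against 4.44 in the authors' deposited table. The neuron list lay at percentile 98.2 with a median of 0.24, led in the authors' deposited table by Stmn2 (1.97 against 0.92, adjusted p = 0.0607, the single member of 20 that passed when adjusted over the list alone) and Gad1 (1.56 against 0.21), and the list took 0.00385% of the sum in Meth and 0.00315% in Saline. Its percentile was 92.07 with the GC and length trend removed. The endothelial and mural list lay at percentile 1.03 with a median of -0.10, including Cdh5 (1.31 against 3.11 in the authors' deposited table) and Kdr (0.61 against 2.27), and at 16.61 when restricted to members above the median level. Percentiles of the other marker lists were 43.88 for astrocytes, 38.45 for oligodendrocytes, 42.68 for their precursors, 51.32 for border-associated macrophages, 7.86 for monocytes and neutrophils, 47.82 for lymphocytes and 2.6 for erythroid cells (1.46 by means and 1.96 with the GC and length trend removed). Called members of marker lists in the authors' deposited table were Abcb1a (0.20 against -0.10), Cxcr2 (0.07 against -0.03) and Lyz1 (0.28 against 0.06), all higher in Meth and near 0. Adjusted over the list alone, members passed in the oligodendrocyte (1 of 15), oligodendrocyte precursor (2 of 12), endothelial and mural (1 of 18) and monocyte and neutrophil (2 of 18) lists. In all, 4 of the 30 lists lay outside the central 95%. If list members were independent genes, 1.5 would by chance. Members of a list can vary together, so the count is no test.

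Of 4 families of chemosensory receptors, which detect odours and pheromones, 3 had mostly higher averages in Meth, at very low levels, and Vmn2r did not. Of the 1057 olfactory receptor genes (Olfr) in the authors' deposited table, 649 had a higher and 34 a lower Meth average, and 98 were among the called genes. The mean log2 average over the family was 0.160 in Meth and 0.024 in Saline. Type 1 vomeronasal receptors (Vmn1r) were higher for 78 genes and lower for 1, and trace amine receptors (Taar) for 9 and 0. Type 2 vomeronasal receptors (Vmn2r), whose coding sequence is split over several exons, were higher for 3 and lower for 5 in the authors' deposited table. Outside these families, coding genes with a single exon and both averages under 1 were higher for 225 and lower for 54, and those with several exons for 1404 and 1420.

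**Figure D3:**
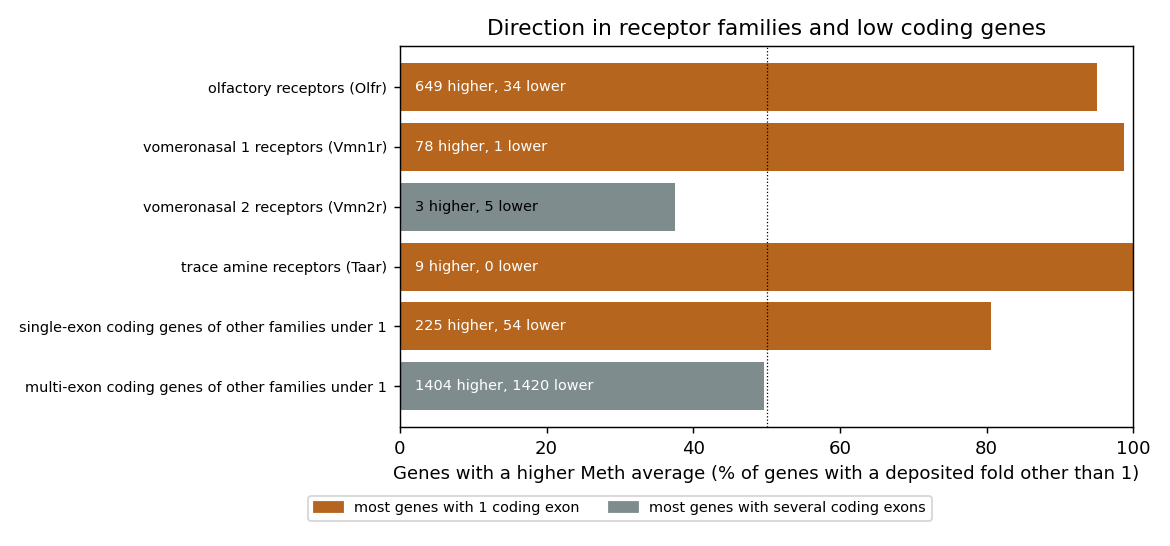
Bars give the percentage of genes with a higher Meth average among genes with a deposited fold other than 1, for 4 receptor families and for other coding genes with both averages under 1, with the numbers of genes written in. Families in which most genes have 1 coding exon (brown) lie at or above 80.6%, and those with several (grey) at 37.5% and 49.7%; the dotted line marks 50%.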

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

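The adjustment over genes with either average of at least 1, the calls without a negative Saline average and both removals of a GC and length trend were chosen after the data were seen. No paired analysis was possible because the deposited table holds no values per sample; for the same reason other normalizations, pseudocounts and tests, leaving out each replicate, a fit of sets with an estimated correlation, fry and other splits of the 6 samples were not run. Adjusted over genes above the median level, over genes with a mean of at least 10, or over genes with either average of at least 1, the deposited p-values left 0 calls (0 higher, 0 lower) against 536, because the near-zero genes that carry the small p-values were no longer in the set; 1632, 1073 and 1520 genes of these sets had an unadjusted p under 0.05, and the lowest adjusted p-values were 0.0789 (Hlf), 0.208 (Txndc9) and 0.0685 (Hlf). Without genes whose Saline average is below 0, 52 of the deposited calls were left (31 higher, 21 lower). Their adjusted p was kept as deposited, with the omitted genes still in the adjustment, and was not recomputed. A minimum fold of 1.5 left 45 (31 higher, 14 lower), an adjusted p under 0.1 gave 618 with 54 lower, and an unadjusted p under 0.05 gave 2426 (1527 higher, 899 lower). Counts stayed within 1.5 times of the deposited ones with an adjustment computed here (540) and without genes at 0 in both groups (564).

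The homeostatic list kept its side of the central 95% under every alternative run, with percentiles from 0.0 to 0.01. The activation list did under each except the trend fitted on genes with an average of at least 3 and removed from all genes (94.96). That setting also shifts genes near 0, while 23 of the 25 members had an average of at least 1 in either group. The number of lists outside the central 95% was 15 with unmatched random lists and 8 with means, against 4. Unmatched random lists moved 11 lists outside, with TNF and NF-kB signalling at 99.9, the cell cycle at 99.86, immediate early genes at 0.01, the circadian clock at 0.05, lysosome and phagocytosis at 0.33, oxidative phosphorylation at 99.98, cholesterol metabolism at 0.11, actin cytoskeleton at 0.14, interferon response at 0.37, unfolded protein response at 99.63 and ribosomal proteins at 97.9. Means put cytokines at 98.06, the cell cycle at 98.85, immediate early genes at 1.71 and erythroid markers at 1.46. Members above the median level put the cell cycle at 97.82 and endothelial markers at 16.61. With the trend removed, cytokines lay at 98.35, immediate early genes at 1.72, erythroid markers at 1.96 and neuron markers at 92.07; with the trend of genes at 3 or above, cytokines lay at 98.54, the cell cycle at 99.83, immediate early genes at 1.16, lysosome and phagocytosis at 1.22, neuron markers at 90.73 and endothelial markers at 2.69. Unmatched random lists draw on all 23930 genes, 6844 of them at 0 in both groups, and so ignore the level of the members. The cause of the shifts in percentile was not tested. The Meth minus Saline difference of marker shares was -0.0064 percentage points, and -0.016 without the 50 most abundant genes.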

Other observations

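The DNA replication and ribosome biogenesis lists and the tests of explanations in this part were chosen after the values were seen; the homeostatic and activation lists were fixed before. DNA replication genes were higher in Meth as a group: in the authors' deposited table, 31 of 38 members were higher and 7 lower, with a median log2 difference of 0.70, above 10000 matched random lists (central 95% from -0.27 to 0.24). Uhrf1, which recruits the maintenance DNA methyltransferase to replicated DNA, stood at 4.04 against 1.40 (adjusted p = 0.1325), Prim1, the primase subunit, at 3.73 against 1.81, and Pole, a replicative polymerase, at 2.16 against 0.43 in the authors' deposited table, while Mcm3 stood at 3.26 against 5.32 and the proliferation marker Mki67 at 0.04 against 0.26. Ribosome biogenesis genes were higher as well: 29 of 38 were higher and 8 lower, with a median of 0.45 at percentile 99.9, including Nop56 (8.60 against 6.99), Noc2l (6.51 against 5.18) and Nop16 (6.77 against 5.46) in the authors' deposited table. With the GC and length trend removed, the medians were 0.69 and 0.41. The members were collected after some of these genes had been noticed, so the percentiles are no independent evidence.

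The first pattern is that most calls fall on genes near 0 with a Saline average below 0. Averages below 0 by more than the rounding step of 0.01 occur 1251 times, which rules out plain means of values whose floor is 0. Expression raised by the treatment would not tie the averages to each other, yet in 94.2% of the 484 called genes with a negative Saline average that average equals minus the Meth average divided by 2 within 0.01, and 445 of them share 5 p-values. A candidate explanation is a further model term, such as a batch, under which 1 Meth library is set against all Saline libraries. A single read in that library would then be enough for a call. Of 21 designs enumerated, 2 were kept. They give these averages, and for a gene read in a single Saline library a p-value within 0.005 of the deposited one. Their p-value was 0.5585 and the deposited one 0.5582, but this match was a condition of the choice and is no independent test. If the further model term holds, the folds of abundant genes rest on the same Meth library, which values per mouse would decide.

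The second pattern is the higher Meth average of the Olfr, Vmn1r and Taar receptor families. Raised receptor transcription does not account for other single-exon coding genes under 1, of which 80.6% of those with a difference were also higher in Meth. The further model term alone predicts no more single-exon genes among genes at p of exactly 1 than among genes whose values fit a single Saline library, but the share was 8.0 times as large (11.5% against 1.4% of coding genes outside the receptor families). Amplified genomic DNA in 1 or more Meth libraries is a candidate source, since a primer pair within 1 exon also amplifies DNA. Single-exon genes were higher in Meth more often than multi-exon ones (225 of 279 against 1404 of 2824, two-sided Fisher's exact test across genes, p = 2e-24). Genes are not independent replicates, and this p-value does not measure a difference between groups of mice. The difference may rest on 1 Meth library. Other differences in library preparation between the groups remain open.

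The third pattern is the lower homeostatic and higher activation list. With the GC and length trend removed, the homeostatic list stayed at percentile 0.01 (median -0.62 after removal, -0.61 before). That argues against a trend with GC content and length of the longest transcript as its cause. The GC content of the amplified stretches was not examined, and a trend with it stays open. The median of the activation list went from 0.42 to 0.26 (percentile 98.78) or 0.16 (percentile 94.96) with the trend fitted in different ways. For that list the trend and the treatment cannot be told apart. Fewer microglia among the sorted cells would lower all abundant homeostatic genes alike if single genes did not scatter. Of the 10 most abundant members, 4 (Cst3, Csf1r, P2ry13 and Siglech) had a log2 difference above -0.1, against -2.46 for Olfml3 in the authors' deposited table. The scatter of single genes is unknown, so this unevenness does not decide the question. An effect of methamphetamine on the homeostatic list, fewer microglia and a single deviating Meth library all remain open, untested without values per mouse.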
